A study of Mus musculus with 16 samples.

How the data were processed

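The series holds 16 libraries of mouse cardiac myocytes, and 11 of them have a processed file: 6 END-seq peak lists, 3 for each genotype, and 5 lists of lamin A intervals from WT mice. Samples were grouped by the titles and the genotype label. The titles number the mice, and the design text states that the END-seq libraries came from 3 mice of each genotype. Nothing in the labels gives sex, age or batch, or says that the lamin A libraries came from separate animals, so the spread between those 5 may be technical.

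END-seq peaks were called per library, per the file headers and peak names, which have the layout of MACS narrowPeak output. The submitters' processing notes list FastQC, SEACR and DiffBind and the build mm10 for END-seq, and SICER and DiffBind and the build GRCm39 for lamin A, without versions or roles; the aligner is not given in the sources used here. Per the file headers, each peak has the authors' fold change over background, a linear ratio of the peak to its own library's background. The deposited lists also give −log10 p and q values and a score, which is the caller's. The fold was used to describe and rank peaks within lists and, as the rule for named genes required, as a mean over the lists of a group. Folds were not compared between genotypes. Every deposited END-seq peak had a q of at most 0.01, so all were kept, and those on unplaced or mitochondrial sequences were left out. The lamin A files have no header. Their deposited columns hold a score and −log10 values, and a further column whose scale the sources do not give, which was not used. Because peaks exist only where the caller passed, a list grows with sequencing depth and enrichment. Depth is unknown here, so a missing peak does not show that breaks were absent.

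Overlap required at least 1 bp. Peaks of the 6 lists were merged into regions. Jaccard indices were computed in base pairs. A gene was hit when a peak overlapped its span extended by 1000 bp. The plan was 1000 bp upstream, but the gene table used (RefSeq, assembly of the mm10 build) has no strand, so 1000 bp was added on both sides, and the planned promoter alternative was not run. The table has no exons, so sites are described only as inside or outside a gene span. All listed symbols were matched. Coordinates are 1-based.

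Group values were compared by exact permutation tests over the 20 assignments of 3 and 3 libraries, on log2 values for numbers, lengths and widths. Regions and genes exclusive to a genotype were counted over the 10 splits of the libraries. Gene lists were compared with 10000 random lists drawn by permuting genes within 20 bins of gene length, two-sided, with Benjamini-Hochberg adjustment over 32 tests. Lamin A libraries were compared with 1000 circular shifts along each chromosome. Genes were named by a rule set before the data were examined: Lmna and Myh6; the 10 genes hit in all libraries of one genotype and none of the other with the highest mean fold; the 10 such genes hit in all 6 libraries; up to 4 genes per list hit in the most libraries; and the 5 longest shared lamin A domains. Some genes that this rule takes are not reported here. Myom1 and Myom2 fall outside it and were chosen after their values were seen, as were the 2 regions given by position and the genes first named in the closing section.

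The settings varied were a q of at most 0.00001, lists of equal length, autosomes alone, all sequences, an overlap of 50% of the shorter peak or a distance within 1000 bp, at least 2 of 3 libraries, gene bodies alone, all annotated genes, leaving out each library, and the replicate number as a block. For lamin A they were merging within 10 kb, leaving out intervals under 100 kb and leaving out each library. Gene content of lamin A domains and END-seq peaks within them had been planned but were not run, because no GRCm39 annotation was used here and coordinates were not converted between builds. Overlap, list and shift computations were tested on simulated data. For lists of 23 genes with a 2-fold raised hit rate, 45% of 200 passed an unadjusted 0.05, and 1% did so with no raise, among 21887 genes, so the list test misses moderate enrichments. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.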

Results

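END-seq, which maps the ends of DNA double-strand breaks, was carried out on cardiac myocytes isolated by Langendorff perfusion from 3 wild-type (WT) mice and 3 Myh6-Cre:LmnaF/F mice, in which Cre under the promoter of the cardiac myosin heavy chain gene Myh6 deletes Lmna, the gene of lamin A and C, in myocytes (cKO below). Lamin A-associated domains (LADs), the stretches of chromatin bound by the nuclear lamina protein lamin A, were mapped in 5 further libraries of WT myocytes. The 5 IgG libraries of the series were not analysed here. No group is labelled as carrying Cre with intact Lmna, so Cre itself and the deletion cannot be told apart in comparisons of genotypes. The series asks whether transcriptional stress is a source of double-strand breaks. The END-seq lists held 1345, 15458 and 8320 peaks in WT 1, WT 2 and WT 3, and 29743, 13630 and 22317 in cKO 1, cKO 2 and cKO 3, on chromosomes 1 to 19, X and Y. Read totals are not given in the sources used here, so the depth behind each list is unknown. The peaks in the list labelled cKO 1 carry names that begin with WT-4, as do those in the list of WT 3. It is called cKO 1 throughout because its label says so. The numbers of peaks, regions and genes that set cKO apart from WT are also given without it. Counts of regions or genes found in 1 genotype alone rise by construction when a library is left out, so those counts are no check.

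Myocytes of cKO mice had more END-seq peaks on average than those of WT mice, but the groups overlapped and the difference did not pass the exact test. The mean was 21897 ± 8065 peaks in cKO and 8374 ± 7057 in WT (SD, n = 3 each), a geometric mean ratio of 3.74 and a log2 difference of 1.90 (exact permutation test over 20 assignments, two-sided, p = 0.2; the smallest p that 3 mice against 3 allow is 0.1). WT 2 held 15458 peaks, more than cKO 2 with 13630. The peaks covered 3.99 ± 1.44 Mb in cKO and 1.53 ± 1.20 Mb in WT (SD, n = 3 each), a log2 difference of 1.84 with the same exact p of 0.2. Median peak width was 172 ± 4.93 bp in cKO and 168 ± 9.45 bp in WT (SD, n = 3 each; exact p = 0.6). Without WT 1, whose list was the shortest, the log2 difference in peak number was 0.88, and without cKO 1 it was 1.65.

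**Figure D1:**
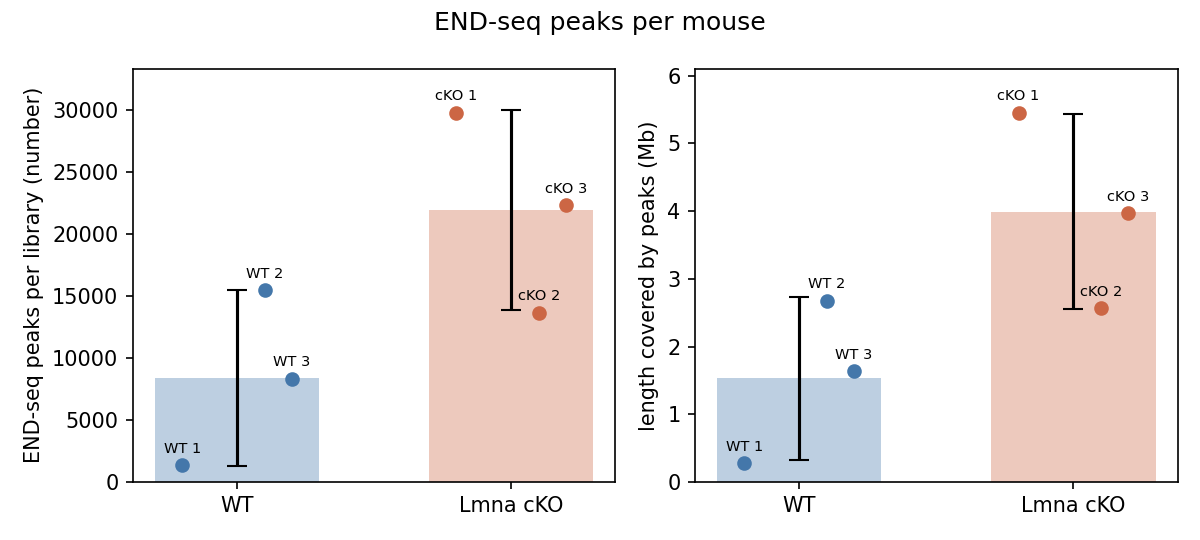
END-seq peaks per library (left, number) and the length they covered (right, Mb) in WT and Lmna cKO myocytes. Points are mice, bars are means and error bars are SD (n = 3 each); WT 2 with 15458 peaks lies above cKO 2 with 13630.

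Many break sites recurred between mice, in both genotypes. The 6 lists merged into 46216 regions, of which 26589 were seen in 1 library and 493 in all 6. Of the regions of WT 2, 80.8% were also found in at least 1 cKO library, and for WT 3 and WT 1 the shares were 60.4% and 61.3%. The Jaccard index in base pairs was 0.389 between WT 2 and cKO 2 and 0.393 between cKO 1 and cKO 3, against 0.252 between WT 2 and WT 3. The order of these pairs depended on how many peaks were taken. With every list shortened to 1345 peaks, WT 2 and WT 3 had the highest index of all pairs, 0.666, and WT 2 had 0.501, 0.574 and 0.658 with cKO 1, cKO 2 and cKO 3. With WT 1 left out and lists of 8320 peaks, WT 2 had 0.314 with WT 3 and 0.530, 0.559 and 0.605 with cKO 1, cKO 2 and cKO 3. Mean overlap was 0.243 over the 6 pairs of one genotype and 0.197 over the 9 pairs of different genotypes, a difference of 0.046 (exact permutation over 10 splits, one-sided, p = 0.2; smallest possible 0.1). Another split of the libraries gave 0.052. The difference turned to -0.025 without cKO 1 and to -0.021 without cKO 3, fell to 0.016 without cKO 2, and rose to 0.175 without WT 2, 0.080 without WT 3 and 0.053 without WT 1. With lists of 1345 peaks it was 0.054, and with WT 1 left out and lists of 8320 peaks, an alternative added after seeing the data, it was 0.098; in both the real split was the highest of the 10 (exact permutation p = 0.1, the smallest possible).

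**Figure D2:**
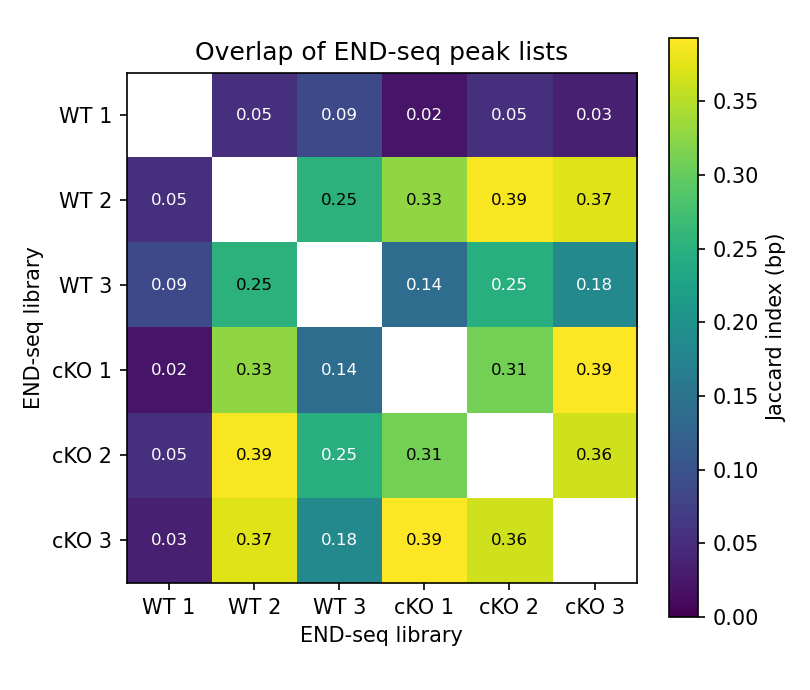
Jaccard index, in base pairs, of each pair of END-seq peak lists (colour and printed value; both axes are libraries). The indices of WT 2 with the 3 cKO lists, 0.328 to 0.389, lie above that of WT 2 with WT 3, 0.252. With equal lists of 8320 peaks they still did (0.530 to 0.605 against 0.314), and with lists of 1345 peaks they did not (0.501 to 0.658 against 0.666).

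Regions with a peak in all 3 cKO libraries numbered 9126, and 7519 of them (82.4%) also had a peak in at least 1 WT library. The other 1607 had no WT peak, whereas 26 regions were found in all 3 WT libraries and in no cKO library. Among these 9126 regions, those without a WT peak were the weaker ones by the authors' fold over background within each cKO list. Their median folds were 20.2, 13.5 and 14.3 in cKO 1, cKO 2 and cKO 3, where all peaks had medians of 15.6, 16.3 and 12.7. Of the weakest 10% of the 9126, ranked within cKO 1, cKO 2 and cKO 3, regions without a WT peak made up 42.6%, 52.1% and 53.7%. Of the strongest 10% they made up 0.329%, 0.329% and 0.219%. The region without a WT peak that ranked highest by the mean of the 3 cKO folds lay on chromosome 9 from 41207127 to 41207363 (mm10). It was outside protein-coding genes, with a fold of 49.8 ± 8.99 (SD, n = 3). The next lay on chromosome 15 from 50533989 to 50534274, also outside protein-coding genes, with 49.2 ± 8.13 (SD, n = 3). The count was 5197 without WT 2, 5175 without cKO 2, 2421 without cKO 3 and 1856 without cKO 1, and it was 67 with every list shortened to 1345 peaks. Leaving out a library loosens the condition, so the count then rises by construction. The reverse count of 26 was 141 without WT 1, 88 without WT 2 and 71 without WT 3.

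**Figure D3:**
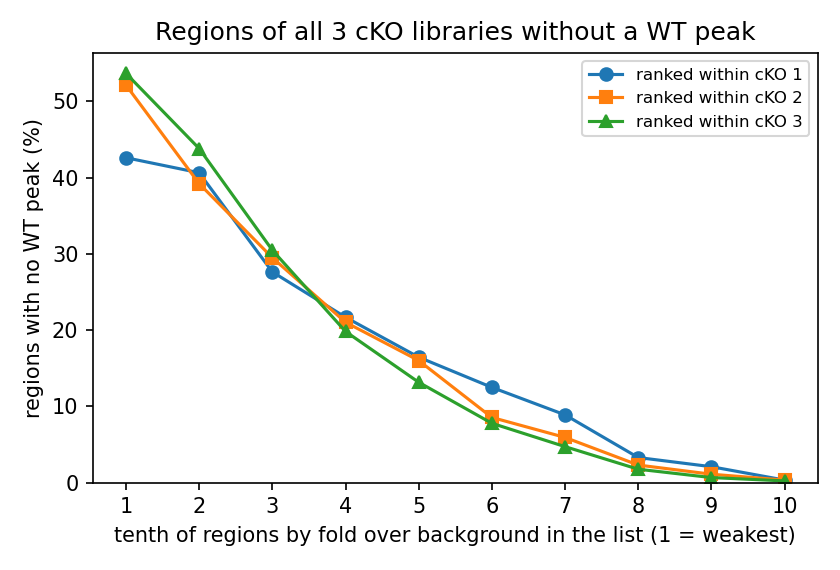
Share of the 9126 regions found in all 3 cKO libraries that had no WT peak (y axis, %), in 10 equal bins of fold over background within each cKO list (x axis, 1 is the weakest). The share falls from 42.6%, 52.1% and 53.7% in bin 1 to 0.329% or less in bin 10.

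The gene targeted by the deletion had few peaks. Lmna (chromosome 3, 88481148 to 88509932, mm10) had 1 peak in cKO 1 and none in the other 5 lists, and Myh6 (chromosome 14, 54941921 to 54968017) had 1 peak each in cKO 1 and cKO 3 and none elsewhere; a peak list does not measure the deletion itself. Among 21887 protein-coding genes, 314 had a peak in every cKO library and in no WT library, and 2 had the reverse pattern. The 314 genes included 282 on autosomes and 32 on chromosome X. Chromosome X held 2.37% of the peaks of WT 2, against 6.15% in WT 3 and 6.25% in WT 1. Among the 10 genes with the highest mean fold were Fndc3c1 on chromosome X (106420041 to 106485577), with a highest fold of 42.2 ± 5.10 (SD, n = 3), and Pnp, which encodes purine nucleoside phosphorylase (chromosome 14), with 40.4 ± 4.36 (SD, n = 3). Others among the 10 were Cylc1 on chromosome X, the translation initiation factor gene Eif2s1, Gpd2, which encodes mitochondrial glycerol-3-phosphate dehydrogenase, Sez6l, the adenylate kinase gene Ak8 and the catalase gene Cat, with mean folds from 37.2 to 31.8. The 2 genes hit in all WT and no cKO libraries were Tmx4 and Ranbp3l, each with 1 peak per WT library. The number of genes hit in all cKO libraries alone was 1361 without WT 2, 1051 without cKO 2 and 362 without cKO 1, and 18 with lists of 1345 peaks. Here too, leaving out a library raises the count by construction.

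Some genic sites of high fold were found in all 6 libraries. There were 274 genes with a peak in all 6 libraries, and the ranking below is among these alone, so it does not compare them with other genes. Vstm4 led them (chromosome 14), with a highest fold of 55.2 ± 11.7 over the 6 libraries (SD), followed by 4930438A08Rik (54.4 ± 12.3), the neural adhesion gene Chl1 (53.8 ± 3.64), the L-type calcium channel gene Cacna1d (53.3 ± 11.8) and Lnx2 (53.0 ± 12.6). The growth factor receptor gene Fgfr1, Lrig3, 2210408I21Rik, Pstpip2 and the sodium/hydrogen exchanger gene Slc9a9 completed the 10. Genes hit in all 6 libraries had a median length of 220 kb, those hit in cKO alone 63.2 kb, and all protein-coding genes 17.2 kb. A longer gene is more often hit by chance, and no expectation from length is given for these groups. Genes with a peak numbered 5356 ± 1595 per cKO library and 2478 ± 2043 per WT library (SD, n = 3 each; exact permutation p = 0.2).

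The share of peaks at genes was close to the share of sequence that genes take up, and the difference between genotypes did not pass the exact test. Within 1000 bp of a protein-coding gene span lay 42.5% ± 1.68 of the peaks in cKO and 37.7% ± 7.65 in WT (SD, n = 3 each), a difference of 4.79 percentage points (exact permutation, two-sided, p = 0.4). Such spans make up 40.1% of the chromosome length between the outermost peaks. Without WT 1, of whose peaks 29.1% lay at genes, the difference was 0.491 points.

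Of the 16 gene lists fixed before the data were examined, the very long, mostly neuronal genes were the most widely hit: all 28 had a peak in at least 2 of 3 libraries in WT and in cKO. In WT that was above the 17.0 expected of length-matched random genes (95% range 12 to 22, permutation of genes within length bins, 10000 draws, adjusted p = 0.0064 over 32 tests). In cKO 26.4 were expected (95% range 24 to 28, permutation adjusted p = 1). With all 28 hit, the cKO test was at its ceiling and could not show an enrichment, so it does not set cKO apart from WT. The WT call was lost when genes were matched in 100 rather than 20 length bins, an alternative added after seeing the data (24.4 expected, permutation adjusted p = 0.241). Examples were Cdh13, a cadherin gene with 1, 18 and 6 peaks in WT 1, WT 2 and WT 3 and 24, 11 and 22 in cKO 1, cKO 2 and cKO 3, Nrxn3, a neurexin gene with 2, 10 and 6 in WT and 15, 6 and 13 in cKO, and Wwox with 1, 7 and 3 in WT and 13, 6 and 10 in cKO. No other list passed the adjusted test in either genotype.

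Genes of the contractile apparatus were hit in 12.7 ± 3.21 of 23 cases per cKO library and in 5.33 ± 5.51 per WT library (SD, n = 3 each; exact permutation p = 0.2, adjusted p = 0.667 over the lists). In at least 2 cKO libraries, 12 of the 23 had a peak against 7.36 expected (permutation adjusted p = 0.242), and in WT 5 had one against 3.18. Csrp3, which encodes muscle LIM protein, Tnnc1 and Tnnt2, which encode cardiac troponin subunits, and Nebl each had a peak in every library but WT 1. Myom1 and Myom2, genes of M-band proteins, had peaks in all 3 cKO and in no WT library, but weak ones, with highest folds of 7.03 ± 0.816 and 8.50 ± 3.49 (SD, n = 3), below the median folds of 20.2, 13.5 and 14.3 in cKO 1, cKO 2 and cKO 3 for shared cKO regions without a WT peak. Ion channel and calcium-handling genes were hit in 12.7 ± 1.15 of 21 cases per cKO library and 7.33 ± 6.03 per WT library (exact permutation p = 0.3), and the 13 hit in at least 2 cKO libraries compared with 13.0 expected. The ryanodine receptor gene Ryr2 was hit in all 6 libraries, with 7, 3 and 9 peaks in cKO 1, cKO 2 and cKO 3 and 1, 6 and 3 in WT 1, WT 2 and WT 3. Of the mitochondrial and fatty acid oxidation genes, 8 of 22 were hit in at least 2 cKO libraries against 4.94 expected (permutation adjusted p = 0.746), Ogdh and Hadha among them.

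In at least 2 of 3 cKO libraries, DNA damage response genes were hit in 4 of 24 cases against 8.65 expected (permutation adjusted p = 0.242). The counts of the lists that follow are on the same basis. Atm and Trp53bp1 had peaks in all libraries but WT 1. Olfactory and vomeronasal receptor genes were hit in at least 2 cKO libraries in 40 of 1465 cases against 57.9 expected (permutation adjusted p = 0.064). Housekeeping genes were hit in 0 of 16 cases in cKO (1.73 expected) and fetal and stress-response genes in 1 of 16 (0.828 expected), the skeletal actin gene Acta1. Nuclear envelope genes were hit in 3 of 14 cases (4.21 expected), with Lmnb1, which encodes lamin B1, and Syne1 in all libraries but WT 1 and Syne2 in cKO libraries alone. Matrix and TGF-beta genes were hit in 5 of 16 cases (5.26 expected), among them Smad3, DNA sensing and interferon genes in 1 of 17 (2.70 expected), and genes of other organs in 2 of 20 (2.18 expected). Markers of other heart cells were near expectation in cKO, with 2 of 10 for fibroblasts (2.02 expected), 3 of 10 for endothelium (4.0), 2 of 9 for smooth muscle and pericytes (2.42) and 1 of 10 for immune cells (2.34); all had a permutation adjusted p of 1. Differences between genotypes in hits per library had adjusted p values of 0.667 or more by the exact permutation test in all 16 lists.

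Lamin A domains in WT myocytes covered 978 ± 278 Mb (SD, n = 5) in 818 ± 406 intervals (SD, n = 5). The 5 libraries held 571, 1116, 360, 692 and 1350 intervals covering 1246, 563, 879, 1212 and 991 Mb. Intervals of at least 1 Mb held 85.7% ± 16.4 of the covered length (SD, n = 5). The libraries shared domains beyond chance: the mean Jaccard index of the 10 pairs was 0.518, from 0.341 to 0.667, against 0.261 on average after circular shifts, and every pair exceeded its shifted values (permutation of 1000 circular shifts, one-sided, adjusted p = 0.001, the smallest they can give). Pairs with WT 2 had indices from 0.341 to 0.403, and the others 0.535 or more. At least 3 of 5 libraries covered 970 Mb, and all 5 covered 355 Mb. The 970 Mb made up 38.9% of the span, which is the length between the outermost intervals of each chromosome.

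The longest domain with every position covered in at least 3 libraries lay on chromosome 5 from 49916201 to 93431999 (GRCm39, 43.5 Mb). The libraries need not be the same along such a domain, so it need not be 1 interval in any 3 of them. The next were on chromosome 1 from 15067001 to 46737599 (31.7 Mb) and from 138841601 to 166348599 (27.5 Mb), on chromosome 3 from 113328001 to 139065799 (25.7 Mb) and on chromosome 7 from 72334001 to 96730999 (24.4 Mb). Chromosomes 3 and 1 were the most covered, at 64.6% and 64.4% of the span, and chromosomes 19, 17 and 11 the least among autosomes, at 1.66%, 17.5% and 20.8%. The span can be shorter than the chromosome. No annotation of this build was used, so genes in these domains are not named, and END-seq peaks, which are on mm10, were not placed in them.

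**Figure D4:**
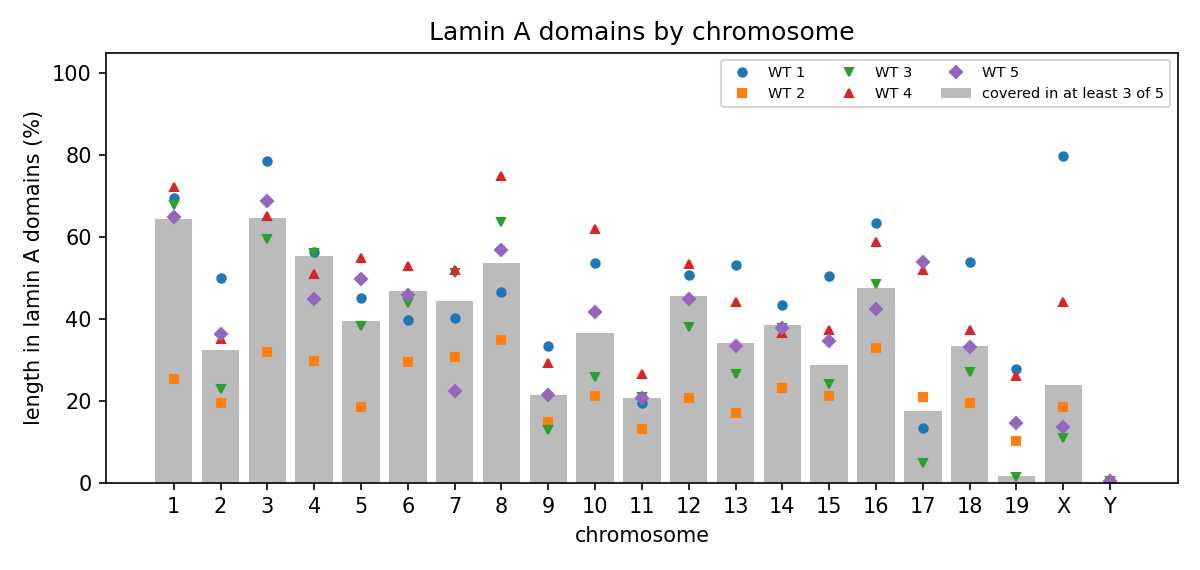
Share of the length between the outermost lamin A intervals of each chromosome (x axis) that lay in lamin A domains (y axis, %). Points are the 5 WT libraries and bars the length covered in at least 3 of them, from 1.66% on chromosome 19 to 64.6% on chromosome 3 among autosomes.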

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

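A sample standing apart from the other lamin A libraries flagged 4 values among 12 measures, where chance flags about 1 in 20. In WT 2, 56.7% of the covered length lay in intervals of at least 1 Mb, against 91.3% in the nearest library, and WT 2 had 961 autosomal intervals against 472. In WT 5, 483 intervals were a lone 200 bp window, against 136, and 860 intervals lay on chromosome X, against 252; 405 of the lone windows in WT 5 were on chromosome X. No explanation was tested for these values.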

How the results depend on the processing

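Alternatives with 100 length bins, gene ends, lists of equal length with WT 1 left out, autosomes alone for genes, and other limits for shared lamin A domains were chosen after seeing the data. Of 147 alternative values, 121 kept the direction of a test, or stayed within the replicate spread or 1.5 times a count, 23 moved further and 3 changed sign. Some of the 121 could not differ. Taking peaks as deposited kept the same peaks, and the replicate block keeps the same mean difference. Merging lamin A intervals within 10 kb joined none. The exact test of cKO against WT used here cannot pass 0.05 with 3 mice each, so its p values say nothing on stability. The depth of the lists is unknown, and how far it limits the count of weak sites was not measured.

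With lists of equal length (1345 peaks), regions in all cKO and no WT libraries numbered 67, the reverse 5 and genes 18. No gene list passed the adjusted test, and 2 tests of a list in a genotype had an unadjusted p under 0.05 by the length-matched test. Peak number is then equal by construction. With WT 1 left out and lists of 8320 peaks, regions numbered 520 and genes 108. With at least 2 of 3 libraries there were 6238 and 248 regions. Within 1000 bp of a gene end, 39 genes were exclusive to cKO and 0 lists passed (0 at an unadjusted p under 0.05 by the length-matched test). With 100 length bins 0 lists passed. Of the 32 tests of a list in a genotype, 5 had an unadjusted p under 0.05 by the length-matched test. The causes were not tested, except that shorter lists and shorter gene windows hold fewer regions by construction.

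Leaving out each library gave log2 peak number differences from 0.88 to 2.64, covered length from 0.87 to 2.51, width from -0.0020 to 0.074, sharing from -0.025 to 0.175 and genic share from 0.491 to 7.83 points. Width changed sign without WT 2 (-0.0020), and sharing without cKO 1 (-0.025) or cKO 3 (-0.021); the cause was not tested. Counts ranged from 1608 to 5197 regions, 35 to 141 reverse regions, 319 to 1361 genes and 1 to 2 tests of lists that passed. Leaving out a library loosens the condition for an exclusive region or gene. Those counts therefore rise by construction and do not measure stability. Regions and genes exclusive to cKO grew most without WT 2 (5197 and 1361) and without cKO 2 (5175 and 1051), and the reverse regions without WT 1 (141). For lamin A, covered length ranged from 911 to 1082 Mb, number from 685 to 932 (441 with intervals under 100 kb left out and 520 on autosomes alone, against 818) and mean Jaccard index from 0.481 to 0.615; domains shared by all 5 covered 355 Mb.

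With the replicate number as a block (paired sign flips, smallest p 0.25), the log2 differences were 1.90 in number, 1.84 in covered length and 0.029 in width, and the genic share differed by 4.79 points (exact p 0.5, 0.5, 0.75 and 0.75). Same-numbered libraries did not deviate together over 2398 windows of 1 Mb (r = -0.020, -0.127 and -0.065), so the numbers were not taken as pairs. The promoter alternative and those on genes or END-seq peaks in lamin A domains were not run. Merging lamin A intervals within 10 kb moved nothing, since all gaps were wider.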

Other observations

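The tests in this part were chosen after the results were seen, except that of lamin A domains and peaks per Mb across chromosomes, and the counts over other splits of the libraries, which were set before the data were examined but whose bounds were written down afterwards. The genes with the most peaks were very long. Macrod2 (chromosome 2, 1998 kb) had 36, 13 and 27 peaks in cKO 1, cKO 2 and cKO 3 and 1, 22 and 8 in WT 1, WT 2 and WT 3. Rbfox1, an RNA-binding protein gene on chromosome 16, had 31, 17 and 17 in cKO and 1, 10 and 3 in WT. Among genes with at least 9 peaks over the cKO lists, the densest were 9530057J20Rik, Sfi1 and Cdc20b, with 31.3, 30.8 and 22.1 peaks per 100 kb, followed by Jph2, which encodes the junctional protein junctophilin 2, with 16.2, and Smyd4 with 15.7.

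Counting peaks rather than genes hit, the contractile genes held 78 peaks over the 3 cKO lists against 43.9 expected of genes of matched length (95% range 26 to 65; permutation of genes within 100 length bins, p = 0.0020, adjusted p = 0.0213 over 32 tests). This count was tried after the planned test of genes hit, which the list did not pass (permutation adjusted p = 0.242), so the enrichment is a hypothesis. Leaving out each of the 23 genes in turn gave permutation p values up to 0.0140, the highest without Actn2, which encodes an alpha-actinin and held 10 peaks; without Ttn, the titin gene, with 17 peaks, it was 0.0126. The peaks were uneven over the list: Ttn, Nebl and Actn2 held 17, 14 and 10 in cKO, and 6 of the 23 genes had none in any library. Without cKO 1 there were 43 peaks against 23.6 expected (permutation p = 0.0058). Without cKO 3 there were 47 against 28.9 (permutation p = 0.0162), and without cKO 2 there were 66 against 35.2 (permutation p = 0.00040). The p values with a gene or library left out are not adjusted for the 32 tests. By library, cKO 1 had 35 peaks (permutation p = 0.0050), cKO 3 had 31 (p = 0.0010) and cKO 2 had 12 against 8.73 expected (p = 0.348). WT 2 had 18 against 10.4 (permutation p = 0.0484) and the WT lists together 24 against 16.3 (adjusted p = 0.532); the difference between genotypes was not tested. The very long genes were the other list past this test, with 962 peaks in cKO against 606 and 385 in WT against 224 (permutation adjusted p = 0.0032 in both); their median length was 1210 kb, and genes of the longest bins still differ in length.

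Regions found in all cKO libraries and in no WT library may reflect longer lists. The real split gave 1607 regions and the highest other split 1982, and for genes 314 and 583; 2 of the 10 splits gave as many in each case, and 10 splits are too few for a share under 0.05. The split with more regions joined WT 2 with cKO 1 and cKO 3, which hold the 3 longest lists. Among the 9126 regions found in all cKO libraries, at most 0.329% of the strongest 10% by fold in a list lacked a WT peak. Of the weakest 10%, at least 42.6% lacked one, as a detection limit would give. A gain of weak sites in cKO could give the same gradient, so the gradient does not decide between them. With lists of equal length the real split gave 67 and the highest other 79 (2 of 10 splits as large). With WT 1 left out and lists of 8320 peaks, the real split gave 520, the highest of the 10, and the next 492. With 10 splits neither can give a share under 0.05, so an effect of Lmna deletion on the number of sites cannot be told apart from list length here. Nor can it be told apart from an effect of Cre, which no group is labelled as carrying without the deletion.

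Chromosome X was over-represented among those regions: 38.8% of X regions found in all cKO libraries had no WT peak, against 16.6% on autosomes, a difference of 22.2 percentage points. Without WT 2 the shares were 61.7% and 56.7%, a difference of 4.96 points, in line with the few X peaks in WT 2 as a source of most of the excess. A smaller effect of the deletion on chromosome X stays open, and cannot be told apart from a difference in sex (Fisher's exact test over regions, which are not replicates, p = 0.0444). X held 2.37% of peaks in WT 2 and 2.72% in cKO 1, and 5.29% to 6.25% in the others; Y held 1.36% and 1.64% in those libraries, 1.71% in WT 1 (23 peaks) and 0.216% or less in WT 3, cKO 2 and cKO 3. Per Mb, WT 2 held 2.18 peaks on X and 2.33 on Y, and cKO 1 held 4.83 and 5.39. WT 3, cKO 2 and cKO 3 held 3.06, 4.80 and 7.05 on X and 0.198, 0.187 and 0.198 on Y. The sex of the mice is not given in the labels. These values point to males in WT 2 and cKO 1 and females in WT 3, cKO 2 and cKO 3. WT 1, with 0.501 on X and 0.254 on Y, was left unassigned. Sex is thus mixed with the comparison of genotypes on X.

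The list labelled cKO 1 has peak names beginning with WT-4, as has WT 3. A copy of the WT 3 list is argued against by a Jaccard index of 0.141 between them. Y held 1.64% of peaks in cKO 1 and 0.216% in WT 3, as different mice would give. In lists of 8320 peaks, cKO 1 had a mean index of 0.577 with cKO 2 and cKO 3 and 0.391 with WT 2 and WT 3, a difference of 0.186; but WT 2 was also nearer to cKO 2 and cKO 3 (0.559 and 0.605) than to WT 3 (0.314). In lists of 1345 peaks cKO 1 was again nearer to cKO 2 and cKO 3 (0.551 and 0.578) than to WT 2 and WT 3 (0.501 and 0.402), while WT 2 was nearest to WT 3 (0.666). As the list lengths disagree on WT 2, whether cKO 1 is another WT mouse cannot be told apart from a wrong name. Without cKO 1 the log2 difference in peak number was 1.65, the genic share differed by 3.99 points, and 1856 regions and 362 genes were exclusive to cKO. The counts of regions and genes rise by construction when a library is left out, so they are no check on cKO 1.

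Chromosomes with more lamin A domains did not hold more END-seq peaks. Over the 19 autosomes, Spearman's rho of the shared domain percentage (GRCm39) and peaks per Mb (mm10) was below 0 in all 6 libraries. It ran from -0.675 in cKO 3 to -0.089 in WT 1, against the prediction of a positive relation. The domain percentage is of the span between the outermost intervals, which can be shorter than the chromosome. In cKO 3, Pearson's r was -0.639 (permutation p = 0.0033, adjusted p = 0.0132), rho had a permutation p of 0.0019 (adjusted p = 0.0088), and r without the 2 chromosomes farthest from the median was -0.671. Adjusted p values for rho were under 0.05 in WT 2, WT 3, cKO 1 and cKO 3 (0.0088, 0.0287, 0.0287 and 0.0088) and not in cKO 2 (0.215) or WT 1 (0.714). Those for r were 0.0132 in WT 2 and above 0.05 in WT 3 (0.0548), cKO 1 (0.0524), cKO 2 (0.379) and WT 1 (0.918). Chromosomes are not independent samples of animals, and gene density was not tested.

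Overlapping peaks of different libraries often shared an edge to within 1 bp. In pairs without WT 1, 77.7% to 90.9% of overlapping peaks shared their start or end, and 46.9% to 54.7% in pairs with WT 1, against 1.05% to 1.89% for random placement of the same widths. Both edges were shared by 0.718% to 5.10%.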
